A study of Homo sapiens with 6 samples.

How the data were processed

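RNA sequencing libraries of MDA-MB-231 cells, an established human cell line of triple negative breast cancer, were compared after transfection with a control siRNA (siControl) or an siRNA against USP32 (siUSP32) for 48 h. Each group held 3 libraries. Per the labels' protocols, RNA was harvested in Trizol and the libraries were made for an MGISEQ-2000 sequencer. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The siRNA sequences are not given in the sources used here.

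The values deposited by the authors are FPKM (fragments per kilobase of transcript, scaled to the mapped total), per the file headers, with 2 decimals and 1 table per library. Each table lists the same 17646 genes by Entrez identifier and symbol. The genome build was GRCh38.p13, per the submitters' processing notes. The aligner, the counting tool, the annotation and any filter on reads or genes are not given in the sources used here, nor is the handling of strand and of reads that match several genes. Because FPKM divides by transcript length and by the mapped total of each library, it is not a count, and no count model was used. Genes that share reads with a near-identical copy are reported as uncertain. No mitochondrially encoded gene was listed.

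The read depth of the libraries is unknown. Low values detected in at most 3 libraries were compared between libraries for the same gene, on 19 to 34 genes per library whose nonzero values lay within a factor of 1.6. The median ratio to the other libraries lay between 0.962 and 1.06, but that factor limits how far it can lie from 1, so it does not measure depth. Counting intervals were not computed. Pairs of libraries within a group shared identical values for 0.450% to 0.783% of tested genes, so no library was a copy of another.

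Values were analysed as log2(FPKM + 1) for the 12003 genes with a mean FPKM of at least 1 over the 6 libraries. Differences are siUSP32 minus siControl on this scale, which understates the change of genes with low FPKM. Folds are ratios of mean FPKM without the pseudocount. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, no covariate and 2-sided tests. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. For single genes an exact permutation test was also run on the log2 values, for which 3 against 3 libraries cannot give a p below 0.1. On simulated values for these 12003 genes in the comparison of siUSP32 with siControl, the same limma fit recovered 63.6% of 66 genes changed by 0.5, 98.5% of 67 changed by 1 and 100% of 67 changed by 2, and called 9 unchanged genes. Only those genes were changed there, with noise independent between genes. These rates need not hold for the real values, where most genes were called.

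Before the data were examined, 27 gene lists were written from general knowledge, with 736 entries, of which 714 were listed in the files, 2 of them under an older symbol with the same Entrez identifier. The 24 lists with at least 5 measured members were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the 24 lists. A "list test" in the results means this test. The rule for named genes was also fixed then. It took USP32, USP6, YAP1, WWTR1, TEAD1 to TEAD4, CCN1, CCN2 and ANKRD1, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and for each list up to 2 rises and 2 falls with the smallest adjusted p, or up to 4 of each for the YAP/TAZ target list. A few further members were chosen after their values were seen and are said to be so where they appear.

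Gene locations, transcript length and GC content were taken from GENCODE 29 on GRCh38 through Entrez identifiers. The principal transcript with the longest coding sequence was used for each gene, and 11947 of the tested genes (99.5%) had one. It need not be the transcript length the authors divided by. Hydrophobic segments of the encoded protein were windows of 19 residues with a mean Kyte-Doolittle hydropathy of at least 1.6. The log2 difference declined with transcript length, so each library was also corrected for length with a loess curve (span 0.5) through its deviations from the mean of the 6 libraries. This correction, a like one for GC content, and the use of hydrophobic segments were chosen after seeing the data. Length-corrected medians are given beside those of the lists, and length-corrected values for named genes that the correction moved by over 1.5 times.

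Alternatives fixed with the gene lists, ahead of the data, were a pseudocount of 0.1, no filter on low values, a minimum mean FPKM of 5, rescaling of each library to the same sum (TPM), median-ratio scaling, quantile normalization, limma without the trend, array weights, a minimum difference of 1, the replicate number as a block, and leaving out each library in turn. For lists they were camera with an estimated correlation and limma's fry, which tests whether the genes of a list move one way. TPM, summed here over the listed genes, moved the median difference of all tested genes from -0.06 to -0.39, and quantile normalization moved it to 0.10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.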

Results

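Gene expression was measured in MDA-MB-231 cells, a human triple negative breast cancer line with mesenchymal traits, 48 h after transfection with a control siRNA or an siRNA against USP32. USP32 is a deubiquitinating enzyme, and the title of the series names the stabilisation of YAP, a transcriptional coactivator restrained by the Hippo kinase pathway, as its subject. The design therefore asked which transcripts differ when USP32 is depleted, and whether those of YAP and its target genes are among them. These libraries measure RNA and not protein, so the stability of the YAP protein was not tested. Each group held 3 libraries. The FPKM of the 17646 listed genes summed to 689260 ± 4825 in siControl and to 892600 ± 49361 in siUSP32 (SD, n = 3 each), a ratio of 1.295, with no overlap between the groups. The median FPKM was 5.14 to 5.23 in siControl and 3.59 to 3.88 in siUSP32 libraries. Across all genes, log2 values correlated at r = 0.998 within siControl, at 0.996 to 0.998 within siUSP32 and at 0.961 to 0.969 between the groups. These are correlations across genes, which are not independent replicates.

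USP32 (Entrez 84669, chromosome 17, 60179094 to 60422470 on the minus strand of GRCh38) was lower in each siUSP32 library. Its FPKM was 7.5, 7.48 and 8.32 in the siControl libraries and 2.0, 1.88 and 2.01 in the siUSP32 libraries, a 3.96-fold fall in the mean. The log2 difference was -1.56 ± 0.07 (SE, limma adjusted p = 8.57e-08), and an exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. After correction for transcript length the difference was -1.23. USP6, a paralog that arose in part from USP32 and can share reads with it, went from 1.71 ± 0.133 to 0.980 ± 0.106 FPKM (log2 difference -0.45, limma adjusted p = 4.97e-04), a value that is uncertain for that reason. It was 0.05 with the length correction and lost its call after quantile normalization (-0.10).

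The transcript of YAP itself fell. YAP1 (Entrez 10413, chromosome 11, 102110461 to 102233423 on the plus strand of GRCh38) went from 57.8 ± 1.54 to 31.6 ± 4.74 FPKM (SD, n = 3), a 1.83-fold fall (log2 difference -0.86 ± 0.10, limma adjusted p = 3.69e-05), and the difference was -0.51 with the length correction. WWTR1, which encodes the YAP paralog TAZ, was at 24.8 ± 0.773 and 23.6 ± 3.02 FPKM and did not pass the test (log2 difference -0.08, limma adjusted p = 0.453). It was lower with TPM (-0.44, 0.00741) and higher with the length correction (0.25, 0.00515), over a range of adjusted p of 0.00515 to 0.997 in 16 alternatives. Of the TEAD transcription factors, through which YAP and TAZ bind DNA, TEAD1 fell 2.57-fold, from 17.7 ± 0.418 to 6.88 ± 1.19 FPKM, and TEAD3 fell 1.69-fold, from 4.10 to 2.42 FPKM, with a call lost after quantile normalization (log2 difference -0.19). TEAD4 rose from 4.60 ± 0.630 to 6.88 ± 0.422 FPKM (limma adjusted p = 8.52e-04), a call that was lost with TPM (log2 difference 0.19) and with the length correction (0.16). TEAD2 was at 5.39 and 5.65 FPKM (log2 difference 0.05, limma adjusted p = 0.580), and was lower with TPM (-0.27) and higher after quantile normalization (0.40).

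**Figure D1:**
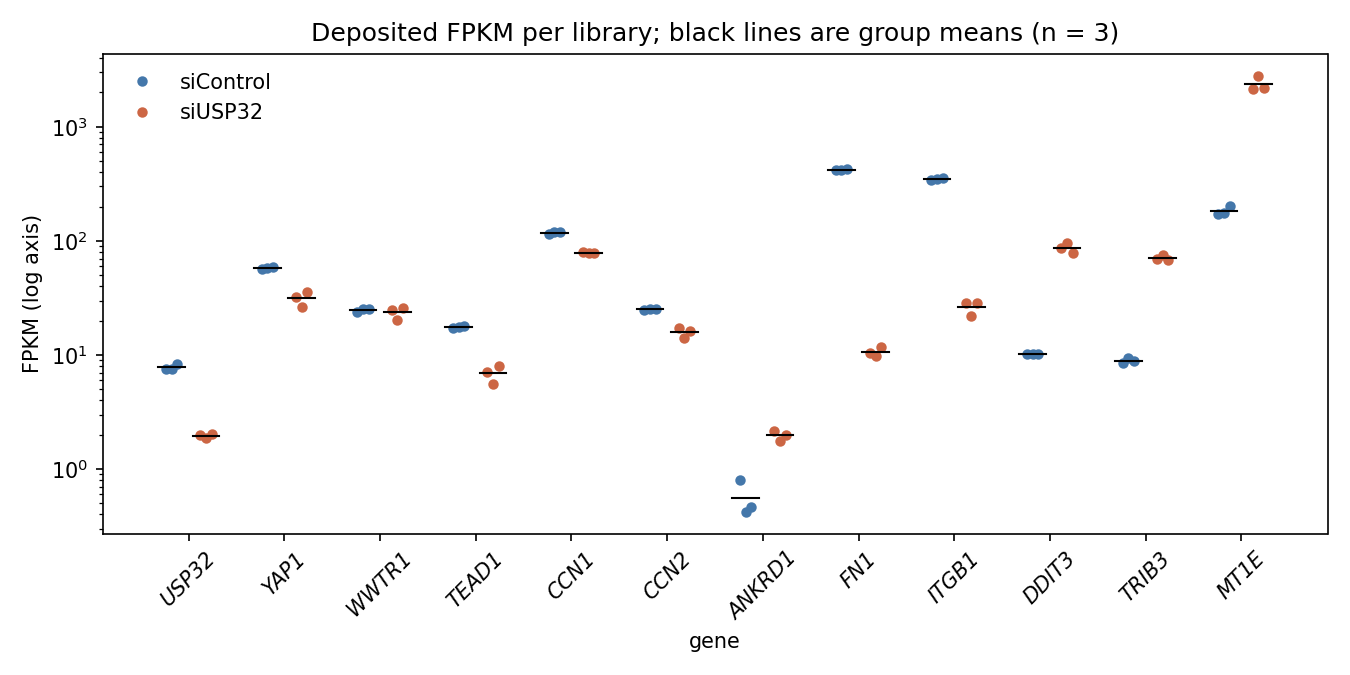
FPKM of 12 genes in each of the 6 libraries on a log axis, with a point per library, blue for siControl and orange for siUSP32, and a black line at the mean of each group (n = 3). USP32 lay at 7.48 to 8.32 in siControl and at 1.88 to 2.01 in siUSP32, FN1 fell from a mean of 421 to 10.6, and MT1E rose from 183 to 2386, while the groups overlapped for WWTR1.

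Of the 12003 genes tested, 8957 differed between siUSP32 and siControl, 4001 of them higher and 4956 lower. The large differences were mostly falls, with 1297 genes lower and 234 higher by at least 1 on the log2 scale. Values of the groups did not overlap for 9340 genes (77.8%, against 10% by chance). The split depended on the filter, with 3577 higher and 3068 lower at a minimum FPKM of 5, and on scaling, with 1716 higher and 7453 lower by TPM and 5253 higher and 3604 lower after quantile normalization, and 163 and 99 of the called genes were called by these scalings in the opposite direction.

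Among the 12 genes with the largest falls, FN1, which encodes fibronectin, fell 39.6-fold, from 421 ± 5.36 to 10.6 ± 1.05 FPKM (SD, n = 3, log2 difference -5.19 ± 0.07, limma adjusted p = 9.27e-10). The matrix glycoprotein gene TNC fell 19.7-fold and the laminin chain genes LAMC1 and LAMA3 fell 18.1-fold and 17.8-fold. Integrin subunit genes ITGA2 (19.1-fold), ITGA6 (16.3-fold), ITGAV (13.4-fold) and ITGB1 (13.2-fold, from 349 ± 8.34 to 26.3 ± 3.97 FPKM) fell with DAG1, the dystroglycan gene, at 14.9-fold and the fibulin gene FBLN2 at 13.5-fold. APP, the amyloid precursor protein gene, fell 14.1-fold, and the complement gene C3 fell 15.7-fold.

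Among the 12 genes with the largest rises, DDIT3, which encodes the transcription factor CHOP, rose 8.53-fold, from 10.1 ± 0.0462 to 86.5 ± 8.24 FPKM (SD, n = 3, log2 difference 2.97 ± 0.07, limma adjusted p = 2.95e-09). TRIB3, a pseudokinase gene induced by CHOP and ATF4, rose 7.99-fold, CHAC1, a glutathione-degrading enzyme gene, 8.92-fold, GDF15, a stress-induced cytokine gene, 8.46-fold, and DDIT4, an inhibitor of mTORC1, 5.81-fold. PHGDH, the first enzyme of serine synthesis, rose 5.49-fold and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 6.93-fold. The metal-binding metallothionein genes MT1E (13.1-fold, from 183 ± 15.3 to 2386 ± 360 FPKM), MT1M (14.6-fold), MT1X (7.27-fold) and MT1F (5.40-fold) rose too, with values that are uncertain gene by gene because this family can share reads. EIF3CL rose from 28.2 ± 8.89 to 222 ± 98.5 FPKM and is uncertain because it is nearly identical to EIF3C.

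The size and sign of the difference went with transcript length. Among the 2390 genes with the shortest transcripts, 217 to 1765 bases, the median log2 difference was 0.43, with 1630 genes higher and 304 lower. Among the 2390 with the longest, 5265 to 43816 bases, it was -0.46, with 212 genes higher and 1724 lower. Each siUSP32 library had a slope against the siControl mean of between -0.411 and -0.293 per doubling of length, while siControl libraries against each other had slopes of -0.00362 to 0.00540. After correction for length 8386 genes differed, 4215 higher and 4171 lower, of which 6541 were also called in the same direction without it and 313 in the opposite one. Length-corrected medians are therefore given beside the gene lists. The correction moved the log2 differences of several genes named below by over 1.5 times. It took those of TAOK1 from -1.21 to -0.60, TAOK2 from -0.66 to -0.42, ZMAT3 from -1.43 to -0.90, OCLN from -1.21 to -0.79, FOSL2 from -0.91 to -0.48 and BMF from -0.57 to -0.28. Those of H2BC12 went from 0.92 to 0.16, H2BC5 from 1.31 to 0.76, SDHB from 0.92 to 0.51, PRIM1 from 0.72 to 0.38, FDPS from 0.70 to 0.39, UBE2L6 from 1.01 to 0.66, RASSF1 from 0.487 to 0.305, ACTA2 from 0.68 to 0.32 and KRT7, which lost its call, from 0.36 to 0.13. Those of ELF3 (0.19 to 0.51), BHLHE40 (0.21 to 0.35) and COL4A1 (0.77 to 1.2) grew.

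**Figure D2:**
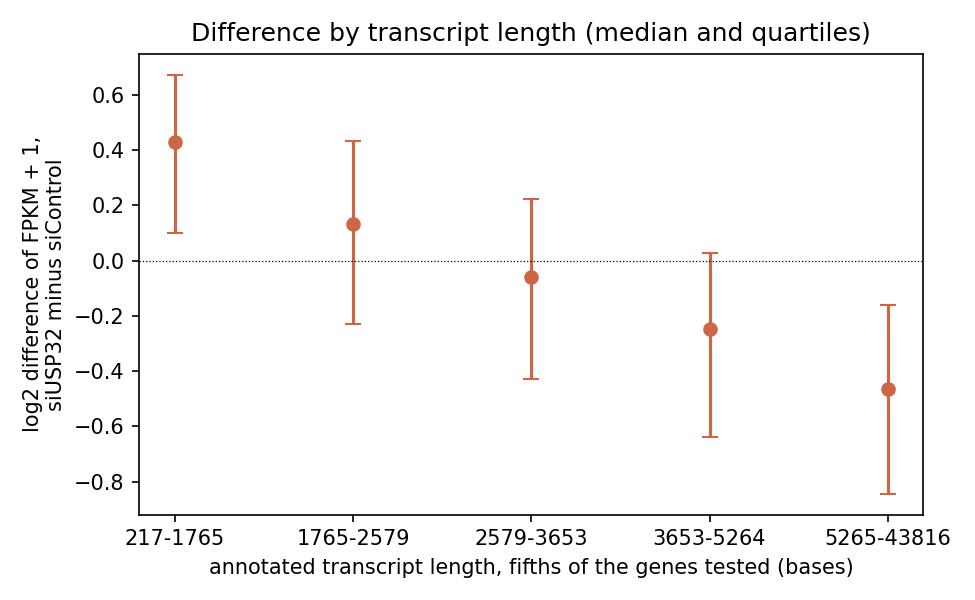
Median (point) and quartiles (bars) of the log2 difference of FPKM + 1, siUSP32 minus siControl, in 5 classes of about equal size of the 11947 tested genes with an annotated transcript, ordered by its length in bases. The median went from 0.43 in the shortest class to -0.46 in the longest.

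For the gene lists, counts adjusted over the list alone equalled those over all genes tested, except for the ubiquitin-specific proteases (5 rose, 31 fell) and the immediate early genes (13 rose, 7 fell). Of the 24 lists tested, 11 passed the list test, 6 higher and 5 lower, and 0 passed with an estimated correlation, whose adjusted p is given with each. A hydrophobic segment was present in 42.9% to 65% of the members of the 5 lower lists. This share was 0% to 46.7% in the 6 higher lists and 32.4% over all genes. Only the YAP/TAZ list was compared with random lists matched on such segments, as described below. Whether the other lists fell beyond genes with a segment was not tested.

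Of 21 measured YAP/TAZ target genes 13 fell, 6 rose and 2 did not pass the test, with a median log2 difference of -0.55. Adjusted over the list alone, the counts were the same. CRIM1, a transmembrane regulator of BMP signalling, fell 11.1-fold, from 49.4 ± 1.18 to 4.46 ± 0.632 FPKM. F3, which encodes tissue factor, fell 4.40-fold, AXL, a receptor tyrosine kinase gene, fell 3.86-fold, and IGFBP3, an IGF-binding protein gene, fell 2.8-fold. The matricellular genes CCN1 and CCN2, widely used as readouts of YAP, fell by less, CCN1 1.49-fold from 118 ± 1.94 to 79.0 ± 1.39 FPKM (limma adjusted p = 3.41e-06) and CCN2 1.58-fold from 25.1 ± 0.155 to 15.9 ± 1.67 FPKM (limma adjusted p = 5.37e-05). ANKRD1, the other common readout, rose from 0.560 ± 0.209 to 1.97 ± 0.186 FPKM (limma adjusted p = 3.54e-05), and NUAK2, a kinase gene, rose 1.81-fold. The proteins of CCN1, CCN2, CRIM1, F3 and AXL have a hydrophobic segment, and genes of that class were lower as a whole, as described below. Those of ANKRD1, NUAK2 and IGFBP3 have none by the rule used. GADD45A rose from 36.6 to 49.0 FPKM and RBMS3 from 1.08 to 1.67 FPKM, calls that were lost with TPM (log2 differences 0.05 and 0.16) and with the length correction (0.10 and 0.16). The list lay lower than other genes by a mean of -0.52 at the threshold of the list test (limma camera adjusted p = 0.0477, and adjusted p = 0.415 with an estimated correlation). It did not pass with TPM (adjusted p = 0.103), with the length correction (0.0800, median -0.25), without siControl library 1 (0.0536) or without siUSP32 library 3 (0.0509), and it passed in 13 of 18 alternatives run with camera (adjusted p = 0.00149 to 0.415). The lowest of these p-values was at a minimum FPKM of 5 (difference -0.90). That filter left out members that rose, ANKRD1, NUAK2 and RBMS3 among them.

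Of 27 Hippo pathway components 15 fell, 4 rose and 8 did not pass the test, with a median of -0.30. With TPM 23 of 27 fell and 0 rose (median -0.63). With the length correction 8 of 26 fell and 9 rose (median 0.03), and after quantile normalization 12 of 27 fell and 8 rose (-0.12). The kinase genes TAOK1 and TAOK2 fell 2.83-fold and 1.64-fold, and RASSF1, a scaffold gene of the pathway, rose from 17.5 to 24.9 FPKM, a call lost with TPM (log2 difference 0.13). The list did not differ from other genes past the threshold (limma camera adjusted p = 0.129). Of 43 ubiquitin-specific proteases other than USP32 itself, 30 fell, 5 rose and 8 did not pass the test, with a median of -0.29. With TPM 35 fell and 1 rose (median -0.61). After quantile normalization 15 fell and 12 rose (median 0.00), and with the length correction 8 fell and 14 rose (0.05). USP34 fell 2.13-fold and USP22 fell 1.54-fold (log2 differences -0.97 and -0.61, length-corrected -0.38 and -0.27), while USP39 rose 1.56-fold and USP21 1.38-fold, the latter with a call lost by TPM (log2 difference 0.09). The list did not pass (limma camera adjusted p = 0.0638), except with no filter (0.0401) and without siUSP32 library 3 (0.0368) among 17 alternatives (up to 0.644).

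Extracellular matrix and adhesion genes fell as a group. Of 25 measured 24 fell and 1 rose, with a median of -2.59 (length-corrected -2.28) and a limma camera adjusted p = 2.27e-10, against adjusted p = 0.0702 with an estimated correlation. COL5A1, a fibrillar collagen gene, fell 9.38-fold from 92.8 ± 1.28 to 9.90 ± 0.546 FPKM, and COL4A1, a basement membrane collagen gene, was the member that rose, from 0.660 ± 0.0625 to 1.84 ± 0.235 FPKM. Of 20 mesenchymal markers 15 fell, 2 rose and 3 did not pass the test, with a median of -1.69 (length-corrected -1.57). FN1 and TGFBI, a matrix protein gene that fell 7.36-fold, were among those that fell. VIM, which encodes the intermediate filament vimentin, rose from 1085 ± 11 to 1658 ± 49.5 FPKM. S100A4 rose from 1683 to 2105 FPKM, but its log2 difference of 0.32 was -0.05 with TPM, -0.24 after quantile normalization and -0.32 with the length correction. The mesenchymal list was lower by the list test (limma camera adjusted p = 6.07e-05, and adjusted p = 0.0958 with an estimated correlation). The transcription factor genes ZEB1 (5.64 and 5.83 FPKM), SNAI1 (2.73 and 3.02) and SNAI2 (8.57 and 7.45), named after their values were seen, were the 3 that did not pass.

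TGF-beta response genes were lower as well, with 19 of 24 lower, 3 higher and 2 not past the test, a median of -1.07 (length-corrected -0.99) and a limma camera adjusted p = 2.39e-04 (adjusted p = 0.0958 with an estimated correlation). The BMP receptor gene BMPR2 fell 9.80-fold and LTBP2, a latent TGF-beta binding protein gene, 7.68-fold. NOG, which encodes the BMP antagonist noggin, rose 2.10-fold, and BHLHE40 rose from 37.5 to 43.7 FPKM, with a log2 difference of 0.21 that was -0.15 with TPM. Of 19 epithelial markers 13 fell, 2 rose and 4 did not pass the test, with a median of -0.41 (length-corrected -0.52). The protease gene ST14 fell 7.29-fold and the tight junction gene OCLN 3.90-fold. The keratin gene KRT7 rose from 1605 to 2064 FPKM and the transcription factor gene ELF3 from 40.7 to 46.5 FPKM, and their log2 differences of 0.36 and 0.19 were -0.01 and -0.18 with TPM, while that of KRT7 was -0.22 after quantile normalization. The epithelial list did not pass (limma camera adjusted p = 0.0551), but passed with the length correction (0.00714), with the replicate number as a block (0.0444), without siControl library 2 (0.0381) and without siUSP32 library 2 (0.0232), and in 9 of 17 alternatives in all (5.00e-04 to 0.415).

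Integrated stress and unfolded protein response genes divided, with 16 of 29 higher and 13 lower and 0 not past the test (median 0.48, length-corrected 0.31). With TPM the median was 0.11, with 14 higher and 13 lower. Those that rose included DDIT4 and PHGDH. Those that fell included chaperone genes of the endoplasmic reticulum, HSP90B1 6.09-fold from 458 ± 8.78 to 75.2 ± 3.13 FPKM and CANX, the calnexin gene, 8.07-fold from 318 ± 4.54 to 39.4 ± 4.10 FPKM. The list as a whole did not pass (limma camera adjusted p = 0.201), though it did with TPM (8.40e-04), the lowest value in 17 alternatives that reached up to 0.924. Lysosome and autophagy genes were lower, with 21 of 35 lower, 9 higher and 5 not past the test, a median of -0.51 (length-corrected -0.68) and a limma camera adjusted p = 0.0233 (adjusted p = 0.185 with an estimated correlation). PSAP, the prosaposin gene, fell 8.22-fold from 264 ± 4.70 to 32.2 ± 2.35 FPKM and SCARB2, a lysosomal membrane protein gene, 8.28-fold. SQSTM1, which encodes the autophagy receptor p62, rose 2.73-fold from 399 ± 5.48 to 1090.4 ± 22.3 FPKM, and WIPI1, an autophagosome gene, 1.68-fold.

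Cytosolic ribosomal protein genes were higher, 38 of 38, with a median of 0.66 that was 0.29 with TPM, 0.10 after quantile normalization, where 20 were higher and 2 lower, and 0.31 with the length correction. RPL4 rose 1.5-fold, though it lost its call after quantile normalization (log2 difference 0.09). The list passed (limma camera adjusted p = 1.98e-11, and adjusted p = 0.415 with an estimated correlation), as it did with the length correction (6.10e-06), the GC correction and every scaling. Of 33 nuclear-encoded oxidative phosphorylation genes 29 rose, 1 fell and 3 did not pass the test (limma camera adjusted p = 2.71e-07, and adjusted p = 0.187 with an estimated correlation). Their median of 0.47 was 0.10 with TPM (14 higher, 7 lower) and 0.12 with the length correction (18 higher, 8 lower). The list did not pass after quantile normalization (limma camera adjusted p = 0.122) or with the length correction (0.0504), and passed in 14 of 17 alternatives (6.55e-10 to 0.187). SDHB rose 1.9-fold and the complex I gene NDUFV1 1.67-fold. SDHC fell from 144 ± 4.26 to 130 ± 9.88 FPKM at a limma adjusted p = 0.0495, a call that was lost in 9 of 16 alternatives, among them leaving out any library but siUSP32 library 3 (0.0672 to 0.147). Its difference of -0.15 was 0.49 with the length correction and 0.02 with the GC correction. Of 26 MYC target genes 21 rose, 3 fell and 2 did not pass the test, with a median of 0.47 (0.10 with TPM, length-corrected 0.41, limma camera adjusted p = 4.59e-05, and adjusted p = 0.155 with an estimated correlation). NOLC1, a nucleolar phosphoprotein gene, rose 2.28-fold and the cell cycle kinase gene CDK4 1.89-fold, while TFRC, the transferrin receptor gene, fell 8.68-fold from 166 ± 0.890 to 19.1 ± 2.78 FPKM and ODC1 1.31-fold. Of 15 replication-dependent histone genes 8 rose and 7 did not pass the test, with a median of 0.50 that was 0.09 with the length correction (limma camera adjusted p = 0.0308, adjusted p = 0.187 with an estimated correlation and 0.757 with the length correction). H2BC5 rose 2.68-fold and H2BC12 1.91-fold, in a family of near-identical genes whose values are uncertain, and the list also missed the threshold at a minimum FPKM of 5 (0.0643), with the GC correction (0.0508) and without siUSP32 library 2 (0.0524), and passed in 12 of 17 alternatives (5.19e-04 to 0.757).

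G1/S genes were higher, with 19 of 35 higher, 7 lower and 9 not past the test (median 0.20, length-corrected 0.22), and they passed the list test (limma camera adjusted p = 0.0185, and adjusted p = 0.415 with an estimated correlation). With TPM 5 rose and 13 fell, the median was -0.16 and the list did not pass (0.103), against 15 of 17 alternatives in which it did (0.00205 to 0.415). MCM7, a subunit of the replicative helicase, rose from 98.1 ± 1.54 to 147 ± 4.09 FPKM and the primase gene PRIM1 1.70-fold, while UHRF1 fell 1.81-fold and E2F8 1.91-fold. G2/M genes were mixed, with 17 of 40 higher, 12 lower and 11 not past the test and a median of 0.08 that was -0.29 with TPM (7 higher, 23 lower) and 0.14 with the length correction (limma camera adjusted p = 0.103). The list passed with no filter (0.0345) and with the GC correction (0.0146) among 17 alternatives (up to 0.784). The centromeric histone gene CENPA rose 2.08-fold and the mitotic kinase gene AURKB 2.34-fold, whereas the proliferation marker MKI67 fell from 16.9 ± 0.291 to 8.36 ± 0.703 FPKM (log2 difference -0.94, length-corrected -0.32) and HMMR fell 1.5-fold. Of 23 p53 target genes 12 rose, 8 fell and 3 did not pass the test, with a median of 0.16 that was -0.17 with TPM (6 higher, 11 lower) and 0.10 with the length correction (limma camera adjusted p = 0.191). GDF15 and SESN2 (3.56-fold) rose, and the death receptor gene FAS (3.49-fold) and ZMAT3 (3.79-fold) fell. Of 13 measured regulators of the BCL2 family 9 rose and 4 fell (median 0.45, 0.09 with TPM, where 4 rose and 4 fell, length-corrected 0.28, limma camera adjusted p = 0.104). The antiapoptotic BCL2L1 rose 1.44-fold and the proapoptotic BID 1.57-fold, and the proapoptotic BCL2L11 and BMF fell 1.74-fold and 1.62-fold.

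NF-kB and inflammatory genes were higher, with 21 of 30 higher, 7 lower and 2 not past the test, a median of 0.57 (0.24 with TPM, length-corrected 0.36) and a limma camera adjusted p = 6.78e-04 (adjusted p = 0.187 with an estimated correlation). The cytokine genes IL1B and CSF2 rose 3.58-fold, from 134 ± 1.38 to 479 ± 12.2 FPKM, and 4.48-fold. The adhesion molecule gene ICAM1 fell 3.44-fold, from 357 ± 0.996 to 104 ± 1.01 FPKM, and PTGS2, which encodes cyclooxygenase 2, fell 3.59-fold. The list missed the threshold after quantile normalization (0.0588) and passed in 15 of 17 alternatives (7.62e-06 to 0.187). Of 34 interferon-stimulated genes 19 fell, 7 rose and 8 did not pass the test (median -0.26, length-corrected -0.22, limma camera adjusted p = 0.183). By TPM 26 fell and 1 rose (median -0.59), and after quantile normalization 7 fell and 9 rose (-0.0171). LGALS3BP fell 2.49-fold and HERC6 2.15-fold, and UBE2L6 rose 2.03-fold and IRF1 1.40-fold, with the call of IRF1 lost by TPM (log2 difference 0.11). Of 25 immediate early genes 13 rose, 6 fell and 6 did not pass the test, with a median of 0.16 that was -0.18 with TPM (7 higher, 12 lower) and 0.18 with the length correction (limma camera adjusted p = 0.0945, and 0.0323 to 0.415 over 17 alternatives, passing with no filter). MYC rose 2.93-fold, from 4.53 ± 0.286 to 13.3 ± 0.883 FPKM, and the phosphatase gene DUSP5 2.09-fold, while FOSL2 fell 2.09-fold and SPRY4 1.97-fold.

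Cholesterol biosynthesis genes divided, with 13 of 25 lower, 11 higher and 1 not past the test and a median of -0.23 that was 0.04 with the length correction (limma camera adjusted p = 0.476). With TPM 14 were lower and 5 higher (median -0.58). FDPS and FDFT1, enzymes of the middle of the pathway, rose 1.64-fold and 1.66-fold. Of 21 glycolysis genes 10 rose, 7 fell and 4 did not pass the test, with a median of 0.13 that was -0.24 with TPM (6 higher, 12 lower), -0.05 after quantile normalization (5 higher, 8 lower) and 0.18 with the length correction and a mean of -0.07 (limma camera adjusted p = 0.316). PFKL rose 2.11-fold and ENO1 from 1849 to 2670 FPKM, although ENO1 was at -0.03 after quantile normalization. The glucose transporter gene SLC2A1 fell 3.81-fold, from 115 ± 2.10 to 30.2 ± 0.425 FPKM, and the lactate transporter gene SLC16A3 2.71-fold. Of 18 hypoxia response genes 10 fell, 5 rose and 3 did not pass the test (median -0.31, length-corrected -0.22, limma camera adjusted p = 0.291). With TPM 14 fell and 3 rose (median -0.67). P4HA2, a collagen prolyl hydroxylase gene, fell 3.51-fold and ERO1A, an oxidase of the endoplasmic reticulum, 2.88-fold, and ADM and NDRG1 rose 1.72-fold and 1.52-fold.

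Markers of other cell types were also measured. Of 7 measured luminal breast cell markers 3 fell, 2 rose and 2 did not pass the test, with a median of -0.14 (0.24 after quantile normalization, where 3 rose and 1 fell, length-corrected -0.07) and a mean of -0.24, although the statistic of the list test pointed higher (limma camera adjusted p = 0.884). The zinc transporter gene SLC39A6 fell 6.75-fold, NAT1 went from 7.24 to 5.84 FPKM with a log2 difference of -0.27 that was 0.04 after quantile normalization, and XBP1 and MLPH rose 1.76-fold and 1.86-fold. Of the immune cell markers 4 were measured and 4 fell (median -0.50, length-corrected -0.83), among them HLA-DRA from 10.6 ± 0.855 to 4.23 ± 0.145 FPKM and CD14 from 7.51 to 4.98 FPKM, a call that CD14 lost after quantile normalization. In that setting 2 of the 4 fell (median -0.30), and with median-ratio scaling 3 did (-0.43). Of the fibroblast and endothelial markers 4 were measured, of which 3 fell (median of the 4 -1.08, length-corrected -0.93), among them LUM from 32.0 ± 0.684 to 7.75 ± 0.443 FPKM and TEK from 2.06 to 0.387 FPKM, and ACTA2 rose from 0.633 to 1.62 FPKM.

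**Figure D3:**
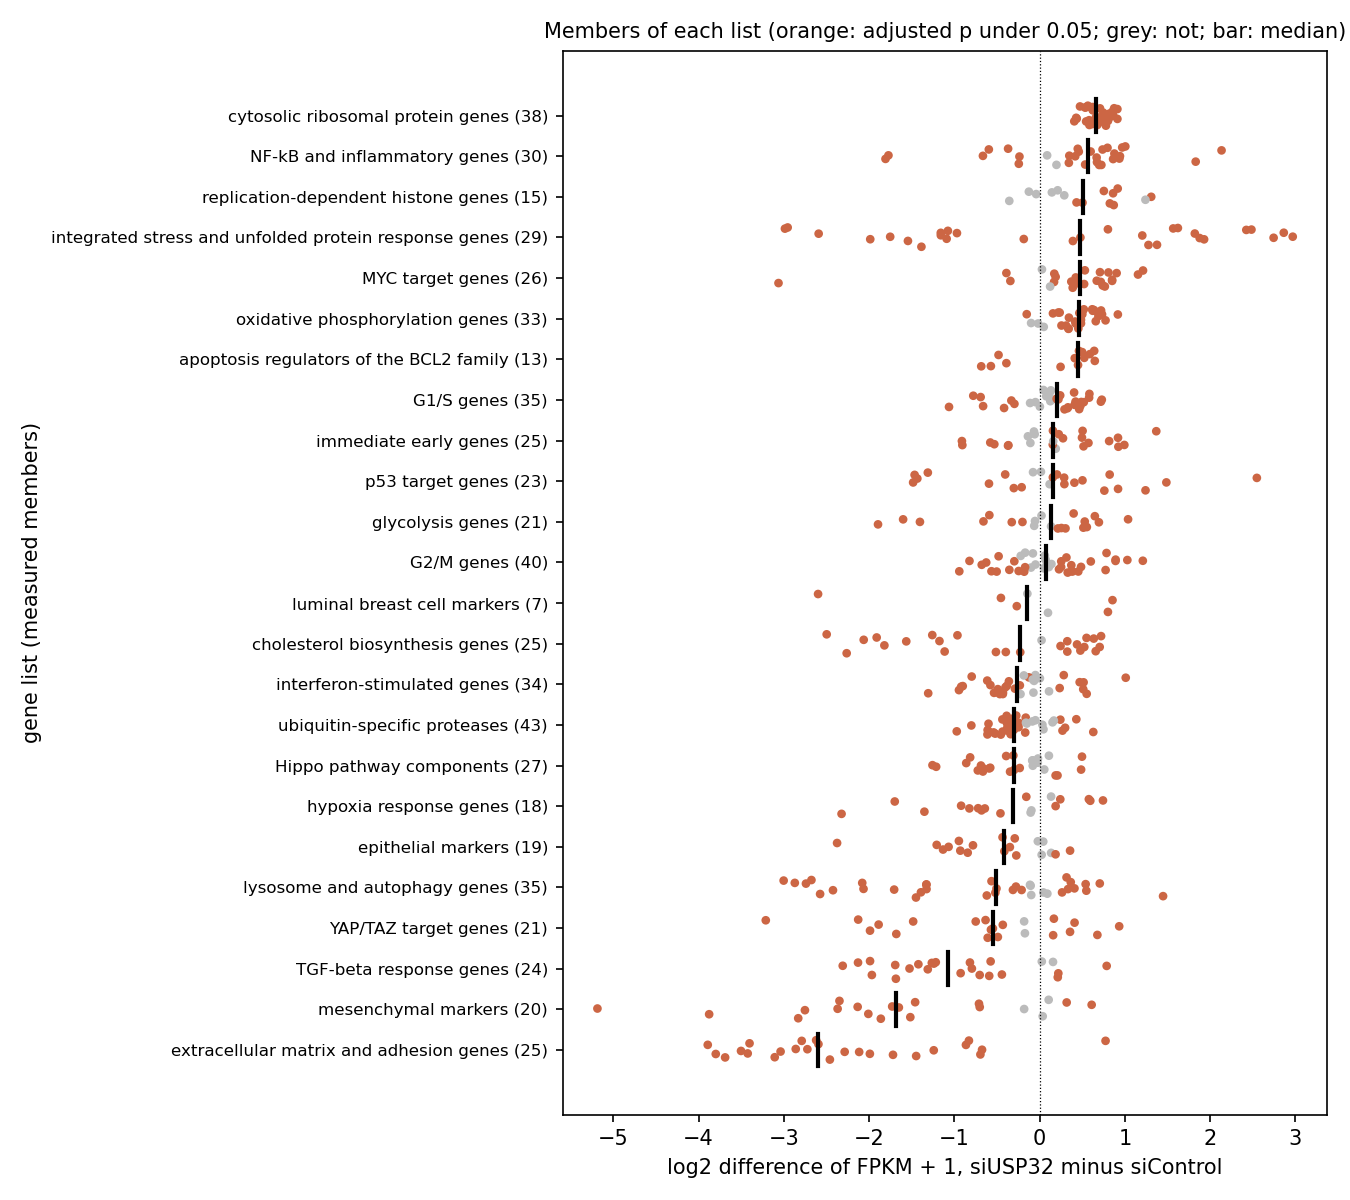
Log2 difference of FPKM + 1, siUSP32 minus siControl, of each measured member of the 24 lists with at least 5 members, ordered by the list's median (black bar), with genes at a limma adjusted p under 0.05 in orange and others in grey. Medians went from -2.59 for extracellular matrix and adhesion genes to 0.66 for cytosolic ribosomal protein genes, and those of the G1/S, G2/M, p53 target, immediate early and glycolysis lists were below 0 with TPM, those of the glycolysis, luminal and ubiquitin-specific protease lists changed sign after quantile normalization (the last to 0.00202), and those of the Hippo, ubiquitin-specific protease and cholesterol lists were above 0 with the length correction.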

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

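The corrections for transcript length and GC content were chosen after seeing the data, and the other alternatives before. USP32 kept its direction and call in the alternatives that could test it (log2 difference -1.94 to -1.22). A minimum FPKM of 5 left out USP32 and other named genes of low FPKM, among them USP6, TEAD3, ANKRD1 and NUAK2. With 1 library left out the USP32 difference was -1.59 to -1.52. Between 8279 and 9291 genes were called, 3692 to 4276 higher and 4556 to 5083 lower, when a library was left out. Raising the minimum FPKM to 5, which tests 8645 genes, left 3577 higher and 3068 lower, so that the balance turned. TPM, which lowers siUSP32 values relative to siControl by the ratio of the library sums, called 1716 higher and 7453 lower. Requiring a difference of at least 1 left 1531 genes, 234 higher and 1297 lower.

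The YAP/TAZ list lay lower than other genes in each alternative, but lost its call with TPM (-0.51, adjusted p = 0.103), with the length correction (-0.42, adjusted p = 0.0800) and with an estimated correlation (-0.52, adjusted p = 0.415). The cause was not tested. With a library left out its difference was -0.53 to -0.49 (limma camera adjusted p = 0.0371 to 0.0536), and the call was lost without siControl library 1 (0.0536) and without siUSP32 library 3 (0.0509). With an estimated correlation 0 of the 24 lists passed, 0 higher and 0 lower. By fry, which asks only whether a list moves one way, 24 passed, 11 higher and 13 lower, so it did not separate these lists.

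Several directions turned, and the cause was not tested beyond what each scaling does by construction. With TPM these were TEAD2 (-0.27), S100A4 (-0.0538), KRT7 (-0.0140), ELF3 (-0.18) and BHLHE40 (-0.15). With median-ratio scaling WWTR1 was at 3.55e-04. After quantile normalization S100A4 was at -0.24, KRT7 at -0.22, NAT1 at 0.0388, ENO1 at -0.0263, and the mean of the glycolysis list minus that of other genes at -0.23. With the length correction these were the Hippo list (0.0705), the ubiquitin-specific proteases (0.16), USP6 (0.0497), WWTR1 (0.25), TEAD2 (-0.0657), S100A4 (-0.32) and SDHC (0.49), and with the GC correction WWTR1 (0.13) and SDHC (0.0166). Leaving out a library moved WWTR1 between -0.142 and 0.0292, the latter without siUSP32 library 2. Over 126 other named genes and 1998 alternative values, 1953 kept direction and call, 25 lost the call, 2 gained it and 18 turned.

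Deviations from the group means of libraries with the same number correlated at -0.077, 0.071 and 0.119. The siControl 1 library correlated best with siUSP32 2 (0.083), while siControl 2 and siControl 3 correlated best with the library of their own number. These values are small, so pairing was neither shown nor excluded. With the replicate number as a block 8995 genes were called, 4016 higher and 4979 lower, and among the lists only the epithelial markers changed side (adjusted p = 0.0444). Read depth is unknown, so the precision of low values could not be computed. The real split of the 6 libraries called 8957 genes, 1 of 10 splits with as many. The other 9 splits called at most 0 by limma (9 to 38 genes at an unadjusted p under 0.05, against 9172). Each of those 9 mixes libraries of both groups on each side, so the group difference widens their spread and holds these counts down. They are therefore no measure of chance, and 10 splits are too few for a share under 0.05.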

Other observations

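Tests of transcript length, GC content, loss in extraction, loss of long RNA and length among genes without a segment were chosen after the result was seen. Those of tail anchors, genomic span and matched lists were fixed before theirs. Genes whose protein carries a hydrophobic segment, as many membrane and secreted proteins do, were lower as a class in siUSP32 libraries. The segment rule misses some secreted proteins, and FN1, COL5A1, LTBP2, LUM and IGFBP3, which fell, stand in the class without a segment. Of 11947 genes with an annotated protein, 3874 (32.4%) had such a segment. Their median log2 difference was -0.43, against 0.06 for the others. It was -0.23 for genes with 1 segment, -0.55 with 2, -0.48 with 3 to 4, -0.88 with 5 to 8 and -1.12 with 9 or more, the multipass membrane proteins. Of 286 genes lower by at least 2 a segment was present in 255 (89.2%), and of 234 genes higher by at least 1 in 37 (15.8%). The integrated stress and unfolded protein response list divided along this line, with 12 of 14 members with a segment lower and 14 of 15 without one higher. In the protein-conducting channel of the endoplasmic reticulum, SEC61A1, which spans the membrane many times, fell 3.03-fold and SEC61B, whose only segment lies at its C-terminal end, rose 1.88-fold, with a log2 difference of 0.24 after the length correction, both named after their values were seen.

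Values of 10 genes of the ATF4 programme and metallothioneins are given here, chosen because they had risen, so that their joint rise tests nothing, and the stress response list written beforehand did not pass. ATF4 rose 3.56-fold, from 135 ± 0.140 to 481 ± 38.8 FPKM (SD, n = 3), and the amino acid synthesis genes ASNS and PSAT1 rose 3.93-fold and 3.72-fold. MT2A rose 4.02-fold, from 2425 ± 107 to 9745 ± 1840 FPKM. Over these 10 genes, DDIT3, TRIB3, CHAC1, MT1E, MT1M and MT1X included, the median log2 difference was 2.8, and it was 2.30 after the length correction and 2.49 with TPM.

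The lower level of genes with a hydrophobic segment, by -0.485 between medians and by -0.495 in each siUSP32 library against the siControl mean, was weighed first. Length and GC content are argued against as its whole cause, since the difference was -0.430 after the length correction and -0.516 after the GC correction, and 0 of 100 shuffles of the class within length bins and 0 of 100 within GC bins reached it. Hydrophobic residues as such are argued against as the whole cause too, since genes whose only segment lies within the first 40 residues (596 genes, length-corrected median -0.66) lay lower than those whose only segment ends within the last 30 (229 genes, median -0.05, against 0.10 for genes without a segment), by -0.611 with a permutation p = 1e-04, the smallest that 10000 permutations can give. The shuffles and the permutation treat genes as independent, and the second class is mixed. It also holds genes of lipid-anchored surface proteins such as NT5E and EFNA1, of other surface proteins such as F3 (-2.22), and of proteins outside membranes such as CCT4 (0.19). After the length correction 40.6% of this second class were called lower. The share was 70.6% for the genes with a segment in the first 40 residues, and 4171 of all 11947 genes were called lower. A loss of RNA translated at the endoplasmic reticulum stays open as a candidate explanation that no value here measured. Loss in the cells and during extraction cannot be told apart, because 3 of 3 siUSP32 libraries show it and the groups were the only difference named, and an effect of the siRNA on other targets was not tested.

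The decline of the log2 difference with transcript length had a rank correlation across genes of -0.518. Genomic span is argued against as its cause, with a partial rank correlation of -0.087 given transcript length, against -0.426 for transcript length given span. The longer transcripts of genes with a segment are argued against as well, since the correlation was -0.584 among genes without one. Loss of long RNA in library preparation cannot be told apart from a change in the cells, because 3 of 3 siUSP32 libraries had a slope below -0.1 and no siControl library did. It may therefore bear on each long gene named as lower, USP32 and YAP1 included, whose differences were -1.23 and -0.51 after the correction.

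The lower level of the YAP/TAZ target list, which the title of the series leads to, was set against these trends. After the length correction its median was -0.25, at percentile 3.96 of 10000 random lists matched on hydrophobic segments and expression level, which had a median of -0.02 and a central range of -0.284 to 0.195. The list thus lay inside that range, near its lower end. The matching used the number of segments and not their position. All genes with 1 segment had a length-corrected median of -0.14, against -0.66 where it lay in the first 40 residues. Secreted proteins that the rule misses were matched as having no segment. The percentile therefore need not hold for lists matched on position or secretion. Among its 11 members with a segment 9 fell and 1 rose without the correction (median -0.75, length-corrected -0.71), and among the 10 without one 4 fell and 5 rose (median -0.01, length-corrected 0.12). The fall of the list thus lay mostly with the members that have a segment. IGFBP3 fell and has none by the rule, but it is among the secreted proteins named above that the rule misses. It is therefore no clear exception. A loss of YAP activity stays open as an explanation that was not tested, and no fall of the list beyond the range of matched lists was shown.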
